A study of Homo sapiens with 16 samples.

How the data were processed

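Affymetrix arrays were hybridised with biotin-labelled RNA amplified from total RNA of MCF7 cells, 3 days after transfection with 20 nM of a scrambled siRNA or of an siRNA against EDI3 (GPCPD1), per the labels' protocols. The labels give a group, a biological replicate number from 1 to 3 and an array letter from A to C for each of the 16 arrays. The scrambled siRNA had 7 arrays and the EDI3 siRNA 9, from 3 biological replicates each. Whether the 3 replicates came from separately grown cultures is not stated beyond the word biological, so p-values measure the spread between these samples. Where a fit was paired by replicate number, p-values measure the spread of the 3 differences between same-numbered samples.

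The deposited table holds log2 expression values for 54675 probe sets. The submitters' processing notes name RMA, which corrects background, normalizes quantiles and summarises probes on the log2 scale; its version, and whether all arrays were normalized together, are not given in the sources used here. Per the deposited values, array medians lay between 5.2 and 5.22 (log2), values ranged from 2.63 to 14.9, and none was missing. Because RMA compresses low signals, fold changes of dim genes are understated. Scanner images were not used here.

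Probe sets were named through the platform annotation, and symbols were checked by gene identifier against RefSeq genes. Of 54613 non-control probe sets, 41091 had 1 gene symbol, 1801 several and 11721 none, and 41037 of those with 1 symbol matched by identifier. The 62 control probe sets were left out of all tests. Probe sets with several symbols or none were not used at the gene level; a probe set without a symbol is unnamed here, which does not mean that it has no gene. The lowest 40% of non-control probe sets by mean signal (below 4.78) were left out as dim. Each gene was represented by its probe set with the highest mean over both groups, chosen without regard to group. Of 19775 genes with a symbol, 14917 were tested. No coordinates are given, since the values carry no genome build.

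Arrays of one biological replicate were averaged on the log2 scale, which gave 6 values per probe set. The comparison fixed before the data were examined was a limma linear model (limma 3.58.1 with statmod 1.5.0, R 4.3.3) with empirical Bayes moderation, two-sided, Benjamini-Hochberg adjusted over all tested genes, and called at an adjusted p below 0.05. The probe sets of GPCPD1 were read from the same fit over all 54613 non-control probe sets, and an exact permutation test was added. Gene lists were tested with camera (preset inter-gene correlation 0.01, lists with at least 5 tested members, adjusted over 20 lists), and again with an estimated correlation and with fry. The lists held 537 genes, of which 467 were tested, 33 were dim and 37 had no probe set naming them alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

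Whether the replicate numbers pair the samples was checked from the data, since the labels only share the numbers. Deviations from the group means, over tested genes, correlated between same-numbered samples with r = 0.821, 0.82 and 0.954 for numbers 1, 2 and 3, all over 0.1, and the first principal component separated number 3. Between different numbers r was 0.567 and 0.592 for numbers 1 and 2, and between -0.822 and -0.812 where number 3 was one of them. The bound of 0.1 was thus also passed between numbers 1 and 2, and the distance of number 3 by itself raises such correlations. Without number 3 the same-number correlation was 0.434, and the different-number one -0.434 by construction, so it comes without a spread. The check therefore shows mainly that number 3 stands apart, and the pairing of numbers 1 and 2 is an assumption. The numbers were taken to pair the samples before calls were compared. The value with the replicate number as a block is printed beside each result it changes. The words rose and fell refer to genes that passed the fit with this block.

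Named genes followed a rule fixed at the same stage. It took GPCPD1 and the tested glycerophosphodiesterases, the 12 largest rises and 12 largest falls by log2 difference among called genes with fully separated groups (filled to 5 per direction by smallest p, as values, where fewer passed), and up to 4 members per list with the smallest p. Because 0 genes passed without the block, a like rule was also applied to the fit with the block. There the same sign in 3 of 3 numbers took the place of separated groups, a condition that all called genes met. That extension was chosen after the values were seen.

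Both fits were tested on 20 simulated sets with 200 of 14917 genes changed, built from the observed means, replicate number effects and residual spread. Without the block, 0% of 1.5-fold, 17.6% of 2-fold and 71.6% of 4-fold changes were recovered, and 0 unchanged genes were called. With the block, 99.2% of 1.5-fold and 100% of 2-fold and 4-fold changes were recovered, and 8.36% of the called genes were unchanged ones, above the nominal 5%. The simulation assumes that the number effect is equal in both groups.

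Alternatives fixed beforehand were the replicate block, other treatments of the technical arrays (all 16 arrays with duplicateCorrelation, with or without the array letter, all as if independent, array C alone, weighted means), no filter or a filter at 60%, subtracted array medians, repeated quantile normalization, the mean of a gene's probe sets, leaving out probe sets of lower specificity, probe sets in place of genes, trended and robust moderation, and leaving out each replicate. Combinations of the block with these, and number 3 as a term, were added after seeing the data. The sequence of the siRNA is not given in the sources used here, so its match to other transcripts was not analysed here.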

Results

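Gene expression was measured in MCF7 cells, an established oestrogen receptor-positive breast cancer cell line, 3 days after transfection with 20 nM of a scrambled siRNA or of an siRNA against EDI3. EDI3 is another name of GPCPD1, a phosphodiesterase that cleaves glycerophosphocholine to choline and glycerol-3-phosphate. Total RNA from 3 biological replicates per group was hybridised to Affymetrix arrays, each replicate to 2 or 3 technical arrays. This gave 7 arrays for the scrambled siRNA and 9 for the EDI3 siRNA. The deposited log2 values had array medians between 5.2 and 5.22. The technical arrays of one biological replicate were averaged, so every comparison rested on 3 values per group, and the number of replicates limits the precision. Same-numbered replicates of both groups deviated together, so each result is given without and, where it differs, with the replicate number as a block.

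The first question was whether the targeted transcript was reduced. GPCPD1 was measured by 3 probe sets. On the brightest the signal was 8.16 ± 0.51 after the scrambled siRNA and 7.13 ± 0.51 after the EDI3 siRNA (log2, SD, n = 3), a difference of -1.03, so that 49.0% of the signal remained. The signal was lower in 3 of 3 replicate numbers, by differences of -1.21, -0.86 and -1.01. The 3 values of one group lay wholly below those of the other, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. In the limma fit over 54613 probe sets the adjusted p was 0.85 without the block and 0.00116 with it. The second differed by -0.56 (67.9% remaining, adjusted p = 0.00891 with the block), and the third, below the dim limit of the gene-level test, by -0.63 (64.7% remaining, adjusted p = 0.016 with the block). Neither passed without the block, where the adjusted p was 1 for the second and 0.597 for the third.

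**Figure D1:**
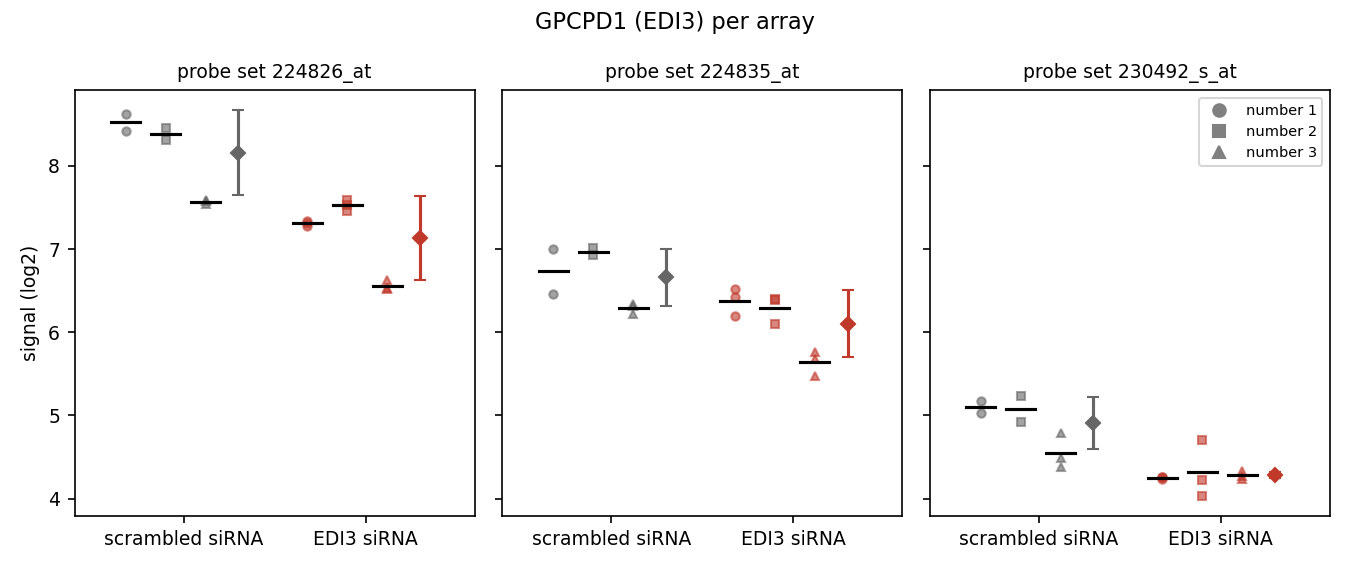
Signal (log2) of the 3 probe sets of GPCPD1 on each of the 16 arrays, by siRNA and replicate number; black bars are the means of one replicate's arrays, and diamonds with error bars the mean ± SD of the 3 replicate means. In the left panel, the brightest probe set, every EDI3 siRNA replicate mean lay below its same-numbered scrambled siRNA mean, with 49.0% of the signal remaining on average.

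The next question was which other genes differed between the siRNAs. The genes that fell furthest in the comparison paired by replicate number were PRNP, which encodes the prion protein, and the acylphosphatase gene ACYP2. PRNP was 6.16-fold lower (log2 difference -2.62 ± 0.67, SD of the 3 within-number differences) and ACYP2 4.82-fold lower (-2.27 ± 0.31). The glutamate transporter gene SLC1A1 fell 4.65-fold, TOMM20, a receptor of the mitochondrial outer membrane import machinery, 4.49-fold, the nuclear lamina gene LMNB1 4.31-fold, the gap junction gene GJA1 4.27-fold and the annexin gene ANXA1 4.14-fold. LINC01293 (4.28-fold), MREG (4.03-fold), the mitochondrial carrier gene SFXN1 (3.92-fold), SUCLG2, a succinyl-CoA ligase subunit (3.90-fold), and ASPH (3.72-fold) completed the 12 largest falls. The largest rises were smaller. NETO2 rose 3.39-fold (log2 difference 1.76 ± 0.36), ZC3HAV1L 3.21-fold (1.68 ± 0.08), the centromere protein gene CENPK 3.13-fold (1.65 ± 0.10), and DR1, a repressor of TATA-binding protein, 3.07-fold. MIS18A, which acts in loading the centromeric histone, rose 3.03-fold, TMEM65 3.02-fold, GCH1, the first enzyme of tetrahydrobiopterin synthesis, 3.01-fold and the TGF-beta receptor gene TGFBR1 2.99-fold. SPRING1 (2.94-fold), the ETS factor gene ELK4 (2.90-fold), PLEKHA1 (2.88-fold) and EP300-AS1 (2.80-fold) followed. All 24 had fully separated groups, with adjusted p between 0.000712 for SLC1A1 and ZC3HAV1L and 0.00515 for DR1 with the block. None of them passed without it (adjusted p from 0.146).

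Without the block, limma called 0 of 14917 genes at an adjusted p below 0.05. The lowest adjusted p was 0.146, and 961 genes (6.44%) had an unadjusted p below 0.05. With the block, 2639 genes passed, of which 1141 rose and 1498 fell. A change of at least 1.5-fold was found for 808 of them (273 higher, 535 lower). At least 2-fold higher were 49 genes and at least 2-fold lower 144. All 2639 had the same sign in 3 of 3 numbers, which passing the paired fit nearly requires, so it adds no support. Of all tested genes, 51.7% had the same sign in 3 of 3, where chance gives 25%. Groups were fully separated for 1598 genes (10.7%). Chance gives 10% for 6 exchangeable samples, and the 3 other splits that part every same-numbered pair gave 1.89%, 2.41% and 2.06%. The genes with the smallest p without the block are given as values only, since none passed. ANXA1 differed by -2.05, LMNB1 by -2.11, EPAS1, a hypoxia-inducible transcription factor, by -1.41, SYBU by -1.32 and AP4E1 by -1.15 (adjusted p = 0.146, 0.146, 0.146, 0.165 and 0.165). On the higher side stood TMEM65 (1.59), LRFN5 (1.00), MFHAS1 (1.19), ACLY (1.08) and CLIP1 (0.88), with adjusted p from 0.167 to 0.216.

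Probe sets of one gene did not always move together. For DR1, whose chosen probe set rose, another fell (-0.33, adjusted p = 0.0409 with the block). The second probe sets of PRNP (-0.15) and SLC1A1 (-0.13) did not pass, and of the 3 others of SPRING1 1 passed. SUCLG2 fell and MIS18A rose on all 3 of their probe sets above the dim limit.

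**Figure D2:**
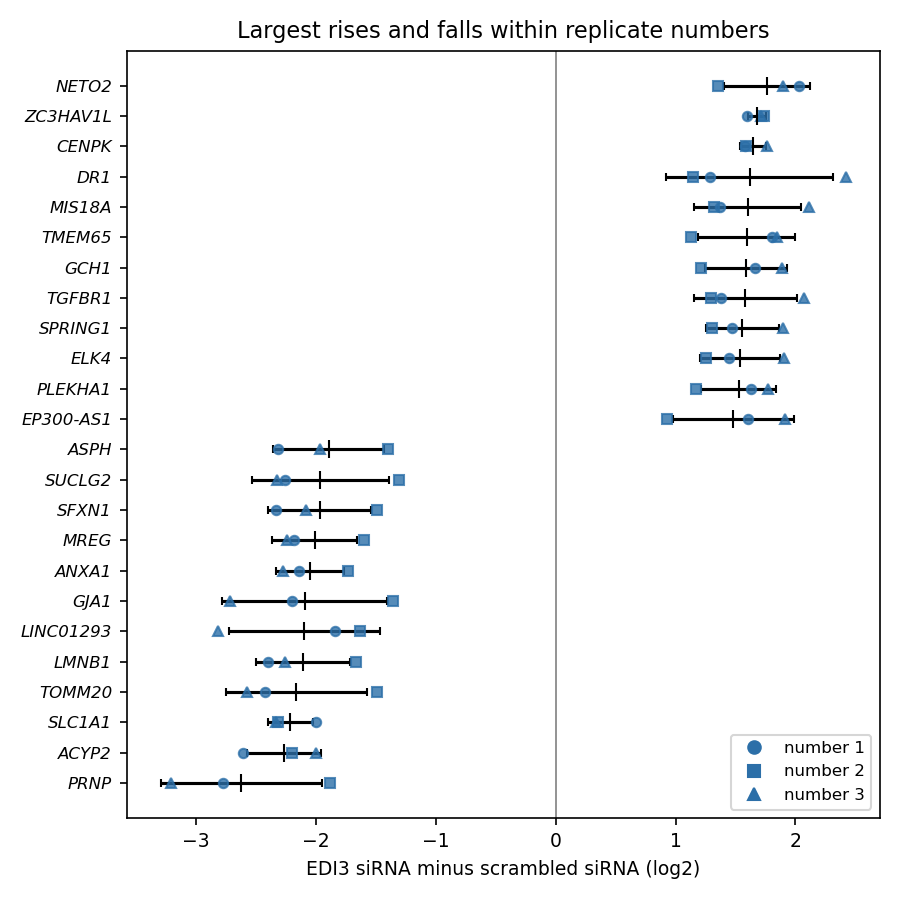
Difference between EDI3 siRNA and scrambled siRNA (log2) for the 12 largest rises and 12 largest falls with the replicate block; symbols are the 3 replicate numbers, bars the mean ± SD of the 3 differences. The averages run from -2.62 for PRNP to 1.76 for NETO2.

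The samples also differed by replicate number. In both groups the arrays of number 3 stood apart from those of numbers 1 and 2. The first principal component (65.7% of the variance) separated number 3, and the second (15.4%) separated the siRNAs. On the second, the EDI3 siRNA arrays of number 2 (4.03 to 8.41) lay nearer to the scrambled siRNA than those of numbers 1 and 3 (17.6 to 21.0). Over all tested genes, number 2 had 18 rises and 83 falls of at least 2-fold. Number 1 had 66 and 195, and number 3 had 118 and 233. Whether the siRNA acted more weakly in number 2 was not tested. Genes differing between number 3 and the other numbers amounted to 7111 (3044 higher, 4067 lower; limma, siRNA as a term). MRPS12 was 17.1-fold, UBE2S 16.1-fold, ID1 13.6-fold and PFN1 9.08-fold higher in number 3, and SAMD12 was 11.5-fold lower; these genes were chosen after their values were seen. Whether the EDI3 siRNA effect itself differed between number 3 and the others was not decided. The interaction called 0 genes in limma, and 123 (0.82%) had an unadjusted p below 0.05, fewer than chance gives. That fit held 1 replicate per group in number 3 and no term pairing numbers 1 and 2, so it could hardly call a difference. Within numbers 1 and 2 alone, 81 genes passed without the block (26 higher, 55 lower) and 739 with it (234 higher, 505 lower). Number 3 holds 1 biological replicate per group and gives no test of its own. With number 3 against the others as a term in place of the block, 1430 genes passed.

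**Figure D3:**
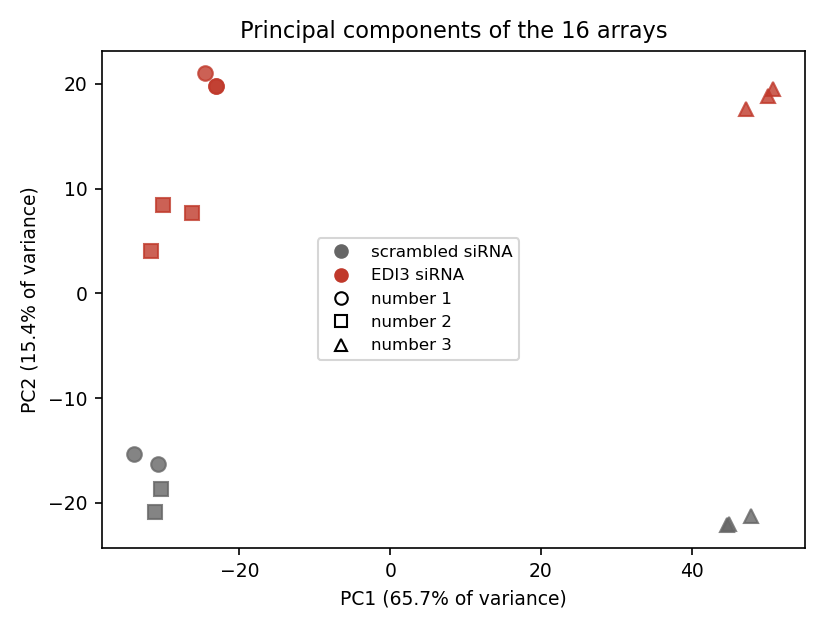
First and second principal components of the 16 arrays over the tested genes; colour gives the siRNA and symbol the replicate number. Number 3 lies apart on the first component (65.7% of the variance), and the siRNAs separate on the second (15.4%).

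The median SD between the arrays of one replicate ranged from 0.0758 to 0.129 (log2) over the 6 replicates. The median SD between replicate means was 0.226 for the scrambled siRNA and 0.214 for the EDI3 siRNA. Between numbers 1 and 2 alone it was 0.108 and 0.10, against median technical SDs of 0.0883 and 0.103 in the same groups. The former are SDs of means over 2 or 3 arrays, the latter of single arrays over all 3 numbers. They are therefore not like for like. The median SD of the 3 same-number differences was 0.128. Across genes, the EDI3 siRNA differences of 2 replicate numbers correlated with r between 0.617 and 0.778. Genes are not independent replicates.

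Gene lists fixed before the data were examined were then compared. Members are counted as risen or fallen where they passed the paired limma fit over all tested genes. Of all 14917 tested genes, 1141 rose and 1498 fell in that fit. Most members of any list would therefore not pass, and somewhat more falls than rises would be found without a shift of the list.

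Among the tested glycerophosphodiesterases, GPCPD1 was not the only one to fall. GDPD1 fell 2.51-fold (-1.33 ± 0.15, adjusted p = 0.00121 with the block, 0.702 without), though its other probe set did not pass (-0.12). GDE1 rose 1.26-fold (0.33 ± 0.08, adjusted p = 0.0234). GDPD2 (0.10), GDPD3 (0.09) and GDPD5 (0.19) did not pass. The list's median was positive (0.10) while its mean was negative (-0.27), and camera did not call it (adjusted p = 0.766 with the block). Adjusted over the list alone, 1 rose and 2 fell.

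Most genes of choline and phospholipid metabolism did not pass, which also held for all tested genes, of which 2639 of 14917 passed. Of 29 choline and phosphatidylcholine genes, 2 rose and 2 fell: the choline/ethanolamine phosphotransferase gene CEPT1 rose 1.36-fold and PEMT 1.31-fold, while SELENOI fell 1.42-fold and ETNK1, ethanolamine kinase, 1.43-fold. Of 22 glycerolipid synthesis genes, 1 rose and 2 fell; the lipid phosphate phosphatase gene PLPP3 fell 1.89-fold and LPIN2 1.35-fold, and PLPP1 rose 1.27-fold. Of 18 genes of lysophosphatidic acid and protein kinase C signalling, 1 rose and 2 fell: PLCB1 rose 1.56-fold, and the receptor gene LPAR6 fell 1.45-fold and PRKCH 1.28-fold. Adjusted over the list alone, the counts were the same for these 3 lists. None was called by camera with the block (adjusted p = 0.829, 0.806 and 0.806). The glycerolipid list had a positive median (0.06) and a negative mean (-0.05).

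More genes of DNA replication and mitosis rose than fell in the paired comparison. Of 35 genes of the G1/S transition and DNA replication, 12 rose and 0 fell, and 20 rose and 2 fell when adjusted over the list alone. GINS1, a subunit of the replicative helicase complex, rose 1.74-fold, the origin recognition gene ORC1 1.59-fold, GINS2 1.52-fold and CCNE2, cyclin E2, 1.43-fold. The list's median difference was 0.26 (log2), and camera with the preset correlation called it without the block (adjusted p = 0.00118) and with it (7.03e-05). With an estimated correlation neither call was kept (adjusted p = 0.648 and 0.74). Of 36 mitosis genes, 10 rose and 2 fell (14 and 3 adjusted over the list alone). AURKB, a mitotic kinase, rose 1.60-fold, UBE2C 1.48-fold, TTK 1.39-fold and BIRC5, survivin, 1.34-fold, while KIF2C fell 1.34-fold and BUB1B 1.26-fold. The mitosis list was called with the block (adjusted p = 0.00851) and not without it (0.118). This call, too, was lost with an estimated correlation (adjusted p = 0.74). Without number 2 the G1/S list was not called in the fit without the block (adjusted p = 0.0735), nor was the mitosis list in the fit with it (adjusted p = 0.059).

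Of the hypoxia-inducible and glycolytic genes more fell than rose in the paired comparison. Of 34 members, 6 fell and 1 rose (10 and 3 adjusted over the list alone). The prolyl hydroxylase gene EGLN3 fell 2.98-fold, HK2, hexokinase 2, 2.21-fold and the mitophagy receptor gene BNIP3L 1.85-fold, and EGLN1 fell 1.28-fold, while ADM rose 1.38-fold. The list's median difference was -0.11 and camera's adjusted p was 0.0123 with the block and 0.118 without. With an estimated correlation the adjusted p was 0.74 with the block, and without number 2 it was 0.059 with the preset correlation.

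Integrin and focal adhesion genes had more falls than rises. Of 32 members, 9 fell and 1 rose (9 and 2 adjusted over the list alone). ITGB8 fell 2.63-fold, ITGB1, the common beta-1 integrin subunit, 2.22-fold, the Rho-associated kinase gene ROCK2 1.97-fold, FERMT2 1.54-fold, ITGA2 1.53-fold and ACTN1 1.21-fold. The list as a whole did not pass camera with the block (adjusted p = 0.333), and its median was -0.0013. Of 24 extracellular matrix genes, 5 fell and 3 rose, with the same counts adjusted over the list alone. COL3A1 fell 2.55-fold, the laminin gene LAMB1 2.17-fold and CCN2, connective tissue growth factor, 2.16-fold, while COL12A1 rose 1.90-fold and TIMP2 1.58-fold (camera adjusted p = 0.51 with the block).

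Lipid synthesis genes moved in both directions. Of 20 fatty acid synthesis genes, 5 fell and 2 rose, also adjusted over the list alone. The desaturase gene SCD5 fell 2.04-fold, ME1, malic enzyme, 1.62-fold and HACD3 1.52-fold, while ACLY, ATP citrate lyase, rose 2.12-fold and the elongase gene ELOVL5 1.43-fold. Of 19 cholesterol synthesis genes, 4 fell and 0 rose (6 and 1 adjusted over the list alone): LSS fell 1.67-fold, HMGCS1 1.51-fold, MSMO1 1.35-fold and IDI1 1.30-fold. The median of the cholesterol list was positive (0.04) while its mean was negative (-0.08). Camera's adjusted p with the block was 0.546 for the fatty acid and 0.669 for the cholesterol list.

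Of 35 genes of the unfolded protein and integrated stress response, 8 fell and 2 rose, also adjusted over the list alone. The cystine transporter gene SLC7A11 fell 2.17-fold, the mitochondrial folate enzyme gene MTHFD2 2.08-fold, CEBPG 1.90-fold and PDIA4 1.25-fold (camera adjusted p = 0.0662 with the block). Of 31 oestrogen receptor targets, 7 fell and 3 rose (10 and 4 adjusted over the list alone). ELOVL2 fell 1.96-fold, FKBP4 1.44-fold, STC2 1.43-fold and RET 1.30-fold (camera adjusted p = 0.242). Of 25 p53 targets, 4 fell and 2 rose (4 and 3 adjusted over the list alone). The death receptor gene FAS fell 2.05-fold, RRM2B 1.90-fold, TIGAR 1.67-fold and FBXO22 1.42-fold on its chosen probe set, while another of its probe sets rose (camera adjusted p = 0.806 for the list), and the list's median was positive (0.02) while its mean was negative (-0.04). Of 25 apoptosis regulators, 2 rose and 1 fell (2 and 3 adjusted over the list alone). PMAIP1, which encodes NOXA, fell 1.64-fold, and BIRC5 and BAD rose 1.34-fold and 1.24-fold (camera adjusted p = 0.669). Of 29 type I interferon response genes, IRF7 alone passed and rose 1.38-fold, also adjusted over the list alone (camera adjusted p = 0.669).

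Cell type markers were measured for the studied line and for other cell types. Of 21 epithelial junction and keratin genes, the desmoglein gene DSG2 fell 3.43-fold, JUP, plakoglobin, fell 1.36-fold and the tight junction gene OCLN rose 1.31-fold. Of 15 mesenchymal and basal-like markers, the transcription factor genes TWIST1 and SNAI2 fell 2.09-fold and 1.96-fold, CAV1 fell 1.79-fold and TGFBI rose 1.77-fold. The signals of TWIST1 and SNAI2 were low, 5.64 and 5.70 after the scrambled siRNA. After the EDI3 siRNA they were 4.58 and 4.73, under the dim limit of 4.78. Adjusted over the list alone, 1 rose and 2 fell among the epithelial genes, and 1 rose and 5 fell among the mesenchymal ones. Of 9 fibroblast markers, COL3A1 fell and the other 8 did not pass, COL1A2 (0.21) and ACTA2 (-0.31) among them. Of 9 leukocyte markers 0 passed, and CD2 (0.14) and LCK (-0.15) had levels of 5.89 and 5.25 after the scrambled siRNA, against a dim limit of 4.78. The counts of these fibroblast and leukocyte lists were the same adjusted over the list alone. Camera called none of the 4 lists with the block (adjusted p = 0.829, 0.378, 0.669 and 0.713).

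**Figure D4:**
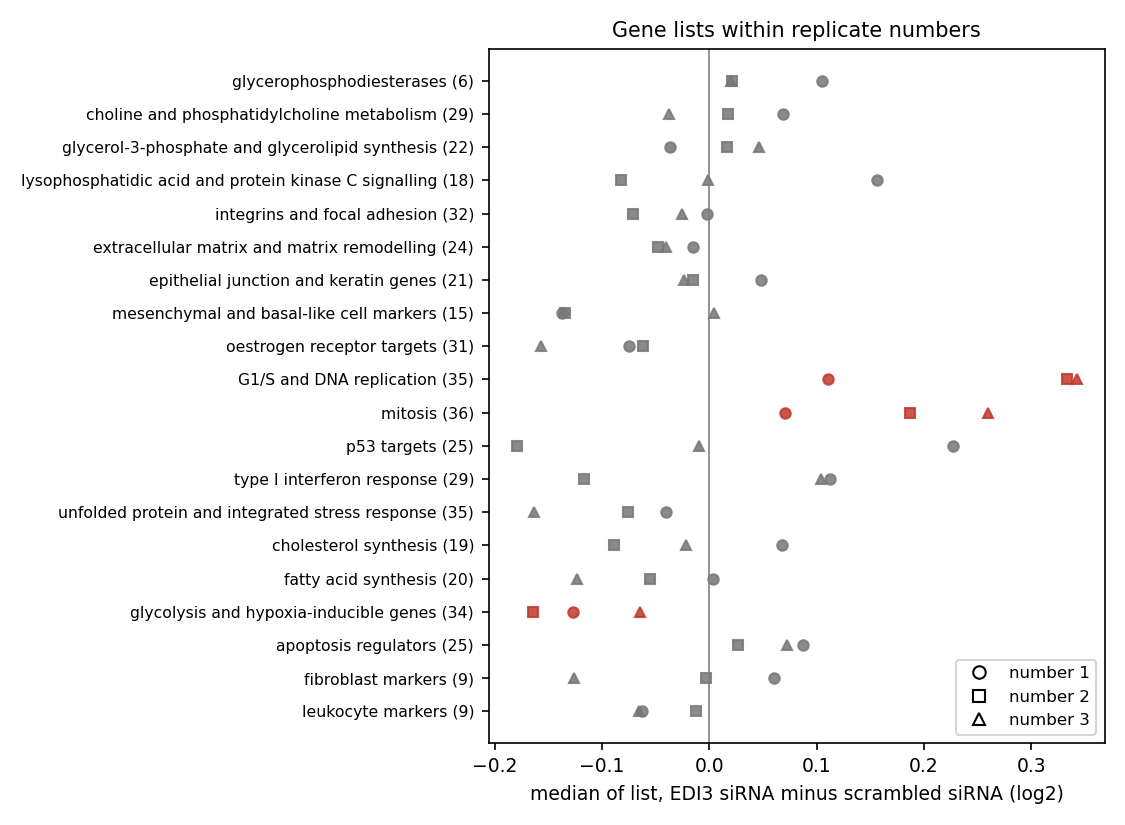
Median difference between EDI3 siRNA and scrambled siRNA (log2) over the tested members of each gene list, for each replicate number; the number of tested members is in parentheses, and red marks lists called by camera with the replicate block and the preset correlation, none of which was called with an estimated correlation (adjusted p = 0.74 for each). The G1/S and DNA replication medians were 0.11, 0.33 and 0.34, and those of the glycolysis and hypoxia list -0.13, -0.16 and -0.06.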

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

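The values of control probe sets in number 3, the fit with the block without number 3, and the split counts at an unadjusted p were chosen after results were seen. The fit that leaves out number 3 without the block and the split counts at an adjusted p were planned. Outliers were not tested, since each group held 3 biological replicates.

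Control probe sets, which are left out of the gene tests, separated number 3 from numbers 1 and 2. The 3' minus 5' signal of ACTB was 3.47 to 3.68 (log2) in numbers 1 and 2 and 1.57 to 1.75 in number 3, a shift of -1.93. That of GAPDH was 1.95 to 2.07 in numbers 1 and 2 and 0.20 to 0.26 in number 3, a shift of -1.78. The excess of 3' over 5' signal was thus larger in numbers 1 and 2, in both groups. The bacterial hybridisation controls, which are added to the labelled sample, were lower in number 3 in both groups, by shifts of -1.30 (bioB), -1.06 (bioC), -0.80 (bioD) and -0.59 (cre). Probe sets with no or several gene symbols were also not used for named genes. Of 6131 above the dim limit, 469 passed with the replicate block (226 higher, 243 lower) and 0 without it (limma).

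No gene passed without the replicate block and 2639 passed with it. A separate hybridisation run for number 3 is a candidate explanation of its distance from the others. All 4 hybridisation controls lay outside the range of numbers 1 and 2, and these do not come from the cells. For bioB, number 3 had 8.23 to 8.30, against 9.40 to 9.71 in numbers 1 and 2. Being added to the labelled sample, these controls do not show whether labelling differed. Labelling and RNA quality, on which the 3' minus 5' shift bears, were not told apart. Number 3 alone did not account for the whole gap between the fits. As a term in place of the block it gave 1430 genes, against 2639 with the block. Without number 3, 81 genes passed without the block, against 739 with it, a gap smaller than that between 0 and 2639 but not closed. The block differs from number 3 as a term only by a further term between numbers 1 and 2. The step from 1430 to 2639 genes therefore came with that further term. What lay behind the differences between numbers 1 and 2 was not tested. A difference of the cultures, such as passage or day, stays open and was not tested.

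The 10 splits of the 6 replicate means into 3 and 3 all gave 0 genes without the block, the real one included, and the highest of the others was 0, too few splits for a share under 0.05. At an unadjusted p below 0.05, the 4 splits that part number 1 or 2 alone and keep number 3 whole gave 1754 to 3396 genes against 961 for the real one, and the 2 that part number 3 alone gave 92 and 196, which points to number 3 as the main structure. The 3 other splits that part all pairs gave 7, 23 and 10. Of the 4 splits that part all 3 pairs, 1 gave as many genes as the real one, which was the real one itself with 2639 genes with the block; the highest of the others was 0, and 4 splits are too few for a share under 0.05.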

How the results depend on the processing

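Combinations with the replicate block, and number 3 as a term, were chosen after seeing the data. Without the block, 0 genes passed, and the count stayed at 0 with weighted means, no filter, a filter at 60%, subtracted medians, repeated quantile normalization, either other summary of probe sets, probe sets in place of genes, and trended robust moderation. The replicate block gave 2639 genes (808 by at least 1.5-fold), all 16 arrays with duplicateCorrelation 356 (332), with the array letter 288 (275), as if independent 1306 (604), array C alone 1 (1) and number 3 as a term 1430 (732). Leaving out a replicate gave 0 to 81 genes and 0 to 81 by at least 1.5-fold, the highest without number 3. GPCPD1 was lower under each alternative run (-1.32 to -0.74 with a replicate left out). It passed with the block (-1.03), with duplicateCorrelation (-1.02), with arrays as if independent (-0.94) and with number 3 as a term (-1.03). With duplicateCorrelation its adjusted p in limma was 0.0498, and with the array letter added it no longer passed (0.1). The fit with arrays as if independent counts technical arrays as replicates.

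One list was called without the block, and the block changed the call of the mitosis and glycolysis lists and of no other list. The block, array C alone and number 3 as a term each gave 3, and with duplicateCorrelation, the array letter, the mean of probe sets or probe sets of lower specificity left out there were 2. With an estimated correlation or fry there were 0. Leaving out a replicate gave 0 to 3 lists. Without replicate 2 of both groups or of the scrambled siRNA, 0 were called.

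With the block, the count of genes moved by over 1.5 times with all 16 arrays (4547), with array C alone (1608) and without number 3 (range over left-out numbers 739 to 2572). Of the 739, 724 were among the 2639. Their sign could not differ, since all 2639 had the same sign in 3 of 3 numbers. The count of lists, 3 with the block, became 0 with an estimated correlation, 5 with fry, and 1 to 4 on leaving out a number. The 5 with fry were the glycerophosphodiesterases, integrins, extracellular matrix, cholesterol and fatty acid lists, not the 3 called by camera. ADCY9 (0.0069) and CXCL12 (0.0698) turned from lower to higher when a gene's probe sets were averaged, without passing. Of the other values of named genes with the block under these alternatives, 1509 kept their side of the threshold, 88 no longer passed and 44 newly passed. A change of direction where neither value passed was not counted apart from the 1509.

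The SD between biological replicates, 0.22, became 0.178 with no filter, 0.255 with a filter at 60% and 0.104 without number 3 (range 0.104 to 0.228 over left-out numbers). Without number 1 or number 2, with as many samples left, it was 0.228 and 0.224. The drop to 0.104 therefore came with leaving out number 3 and not with fewer samples. Under the other filters, other genes enter by construction, and no further cause was tested. Low signal limits the dim genes, among them the third GPCPD1 probe set.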

Other observations

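The values on number 3 and on other probe sets of a gene, the bound by which RNA degradation was judged, and the fits of the G1/S list with the block by an estimated correlation and by fry were chosen after results were seen.

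Among the genes called with the replicate block, other probe sets of the same gene shared the sign of the chosen one in 2206 of 2708 cases (81.5%). Opposite and also called were 32 probe sets of 27 genes, DR1 and FBXO22 among them, where different transcript forms or cross-matching probes were not told apart here. In number 3, 815 genes were at least 2-fold higher and 701 at least 2-fold lower than in numbers 1 and 2, and the shifts in the scrambled and the EDI3 siRNA samples correlated across genes with r = 0.954. CYBA (14.1-fold), NDUFB7 (14.4-fold) and the heat shock gene HSPB1 (9.81-fold) were higher in number 3, and CARMIL1 (10.6-fold), RIT1 (7.39-fold) and SEC22B (6.92-fold) lower. No gene list was called by camera for number 3 (lowest adjusted p = 0.994).

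More genes fell than rose by at least 2-fold after the EDI3 siRNA, 144 against 49 with the block. RNA degradation in one group is argued against by the 3' minus 5' signal, which differed between the siRNAs by -0.012 ± 0.17 for ACTB and 0.014 ± 0.056 for GAPDH (mean ± SD of 3 differences), more than 1 SD under the 0.3 that this explanation was set to need. The bound written beforehand, a difference at or below 0 in at least 2 of 3 numbers for both genes, was met by ACTB only, as the GAPDH difference was positive in 2 of 3. One replicate number alone did not carry the falls, since the ratio over all tested genes was 2.95, 4.61 and 1.97 within numbers 1, 2 and 3. An offset from normalization cannot be told apart from an effect of the siRNA, which stays open and was not tested: the median difference over all tested genes was 0.015 (log2), but RMA had already brought the array medians within 0.026 of each other, so this value decides nothing.

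The list of G1/S and DNA replication genes was higher after the EDI3 siRNA by camera with the preset correlation. With an estimated correlation the call was lost (adjusted p = 0.648 without the block and 0.74 with it), and fry did not call it (adjusted p = 0.142 with the block). Its median difference was 0.11, 0.33 and 0.34 in numbers 1, 2 and 3, so that the rise was not confined to a single number (lowest 0.111). The call did depend on number 2, without which camera did not call the list in the fit without the block. A trend with signal level stays open in number 1: against 10000 random lists matched on mean signal, the list's median lay at percentile 96.7 there, below the bound set in advance, and above all 10000 in numbers 2 and 3. No biological explanation was tested.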
